A study of Homo sapiens with 6 samples.

How the data were processed

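RNA from LX-2 cells, an immortalised human hepatic stellate cell line, was measured by RNA sequencing in 6 libraries. Per the labels' protocols, the cultures had received the solvent DMSO or 5 µM ginkgetin, a biflavone of the ginkgo tree, for 48 h, and libraries of each of the 3 samples per group were made from total RNA with a SMARTer mRNA kit. The labels do not say that the replicates are separate cultures, so the p-values measure only the spread between these samples, which may be technical.

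The authors deposited 1 table of whole-number read counts per gene for the 6 libraries, per the file headers, and these counts were the starting point. The same table holds the authors' CPM, counts scaled to a common library total, for each library and their mean CPM per group, per the file headers. It also holds the authors' log2 fold change, which matches the log2 ratio of their mean CPM values. The authors' deposited p-value and its false discovery rate come from a test whose tool is not given in the sources used here. Columns were matched to samples by name, with the columns headed as controls taken as the DMSO libraries. The aligner, the read counter and the use of strand are also not given in the sources used here. The submitters' processing notes name the mouse builds GRCm38 and mm10, whereas all 36937 rows of the deposited counts carry human Ensembl gene identifiers, so the build behind the counts is open and no coordinate was taken from it.

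Of the 36937 gene identifiers, 36709 matched a current symbol and 36732 were placed in GENCODE version 29 on GRCh38, from which the coordinates, transcript lengths and GC contents were taken. No count was recorded for 12257 genes in any library. Library totals lay between 31508006 and 38350825 counts for DMSO and between 44459165 and 66423514 for ginkgetin, so the ginkgetin libraries held 1.58 times the counts of the DMSO libraries together. The common biological coefficient of variation was 7.19%. Counts of 20 or more per pair of replicates differed by more than sampling noise in all 6 pairs within groups, with a chi-square per degree of freedom between 4.99 and 34.8, and each library was counted as 1 replicate.

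Genes were filtered with filterByExpr of edgeR 4.0.16 in R 4.3.3, which left 14814 genes. The 3 ginkgetin libraries were compared with the 3 DMSO libraries by edgeR's robust quasi-likelihood F test with TMM normalisation, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called changed at an adjusted p under 0.05, and "rose" and "fell" are used of such genes alone. CPM values given here were computed from the counts and the TMM-scaled library totals, and are means ± SD over the 3 libraries of a group unless stated. They are relative to each library's total, so a change in the total RNA of a cell would not be seen. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. For genes with 0 counts in all DMSO libraries the fold was computed against a floor of 3 counts over the DMSO group, which is 0.0289 CPM, and is a lower bound. Where a library was left out, the floor was 3 counts over the DMSO libraries that remained. For genes with 1 to 3 counts in the DMSO group the ratio is given with an exact 95% counting interval. These bounds and intervals cover counting error only.

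In all, 39 gene lists were fixed. They cover stellate cell activation and quiescence, collagens, collagen processing, matrix glycoproteins, matrix proteases, TGF-beta targets, YAP and TAZ targets, contractile genes and growth signalling. Further lists cover the cell cycle, p53 targets, apoptosis, senescence, NF-kappaB, interferon, immediate early genes, NRF2 targets, the ATF4 response, chaperones of the endoplasmic reticulum and of the heat shock response, lysosome, autophagy, iron handling, hypoxia and aryl hydrocarbon receptor targets. The rest cover lipid and cholesterol metabolism, fatty acid oxidation, ribosome biogenesis, ribosomal proteins, the respiratory chain, mitochondrial mRNAs, and markers of hepatocytes, leukocytes, endothelium and epithelium. A list of histone genes had 0 members analysed here and was not used here. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over 35 lists. Camera with an estimated correlation and the self-contained test fry were run beside it. Many of the lists share members, so their results are not independent.

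The groups, the tests, the gene lists, the rule for named genes and the alternatives, other than those said below to be added, were fixed before the data were examined. The rule took the 10 largest rises and the 10 largest falls among changed genes with a mean of at least 50 counts per library and no overlap between the groups. It also took 8 fixed stellate cell genes, and from each described list the 4 members with the smallest p and the member with the smallest p against the list's majority direction. Genes known only by a clone or locus identifier were counted and not named. Genes of the lists were named where camera called the list or at least 1 in 3 of its tested members passed, and the examples printed are among these. The values of 1 gene taken by the rule are not reported here. Of the 155 genes taken by the rule, 31 share exon bases with another tested gene, 10 of them over more than 10% of their exon bases. Since strand is not given, reads in such stretches cannot be assigned to 1 gene. The 10 are ACTA2, BCL2L1, COL18A1, FAU, IGFBP7, KRT18, NDUFB9, NID2, PSMB8 and VIM, and their values are uncertain to that extent.

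The alternatives were DESeq2 size factors in the same test, library totals alone, DESeq2 1.42.0, limma-voom, no filter beyond 1 count, a filter of at least 50 counts in 3 libraries, an absolute log2 fold change of at least 1, an adjusted p under 0.01, the replicate number as a block, and each library left out in turn. An equal-depth run, with each library thinned at random to the smallest total, and offsets for transcript length and GC content were added after seeing the data. The offsets were local regressions with a span of 0.3 on the longest transcript of each gene or on its principal transcript.

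The test was checked on simulated data for the comparison of ginkgetin with DMSO, in 5 draws of 14814 genes with 200 genes changed in each. Of the genes changed by 1 on the log2 scale 84.5% were called, and of those changed by 0.5 on that scale 66.6% were called, with 0 wrong directions. Among the unchanged genes 66 of 71945 were called, which is 8.17% of all calls and above the nominal rate. In the real libraries 68.3% of the tested genes were called, a far larger share, and the adjustment depends on that share. These rates therefore do not carry over to the real comparison. In simulated counts, drawn without correlation between genes, camera called 0 of 35 unchanged lists and recovered the 1 list that had been lowered. Every member of that list was lowered by the same factor, and few other genes changed. This check therefore does not carry over to the real lists either. In the real libraries, 9 splits mixed DMSO and ginkgetin, and in each camera at the preset correlation called 8 to 18 of 35 lists. These splits keep part of the difference between the groups, so their calls do not give a rate of false calls.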

Results

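The data are gene-level read counts from 6 RNA sequencing libraries of LX-2 cells, a human line of hepatic stellate cells, the collagen-producing cells of the liver. In this series 3 libraries came from cells kept in DMSO and 3 from cells given 5 µM ginkgetin, all collected at 48 h. Total counts were 38350825, 31508006 and 34808012 in the DMSO libraries and 44459165, 54205342 and 66423514 in the ginkgetin libraries. The design poses 1 question, which genes differ in mRNA level between cells with and without ginkgetin.

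RSAD2, an antiviral enzyme, rose with ginkgetin from 0.221 ± 0.15 to 476 ± 101 CPM (SD, n = 3 libraries per group), and of 17 tested interferon-stimulated genes 17 rose (camera adjusted p = 9.29e-09; adjusted p = 0.458 with an estimated correlation). ACTA2, the smooth muscle actin of activated stellate cells, rose from 1.48 ± 0.25 to 14.6 ± 1.0 CPM, and in the list of activated stellate cell genes 15 of 19 rose, 2 fell and 2 did not pass (camera adjusted p = 0.00199; adjusted p = 0.458 with an estimated correlation). CDK1, the kinase that drives mitosis, fell from 173 ± 4.7 to 83.4 ± 3.8 CPM, and of 74 genes of the G2/M transition and mitosis 66 fell, 0 rose and 8 did not pass (camera adjusted p = 9.06e-15; adjusted p = 0.458 with an estimated correlation). Of 14814 tested genes 10124 (68.3%) changed, 5238 higher and 4886 lower with ginkgetin, by edgeR's quasi-likelihood test at an adjusted p under 0.05. A change of at least 2-fold was seen in 2791 genes, 1878 higher and 913 lower, and the median size of change among all changed genes was 0.63 on the log2 scale.

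**Figure D1:**
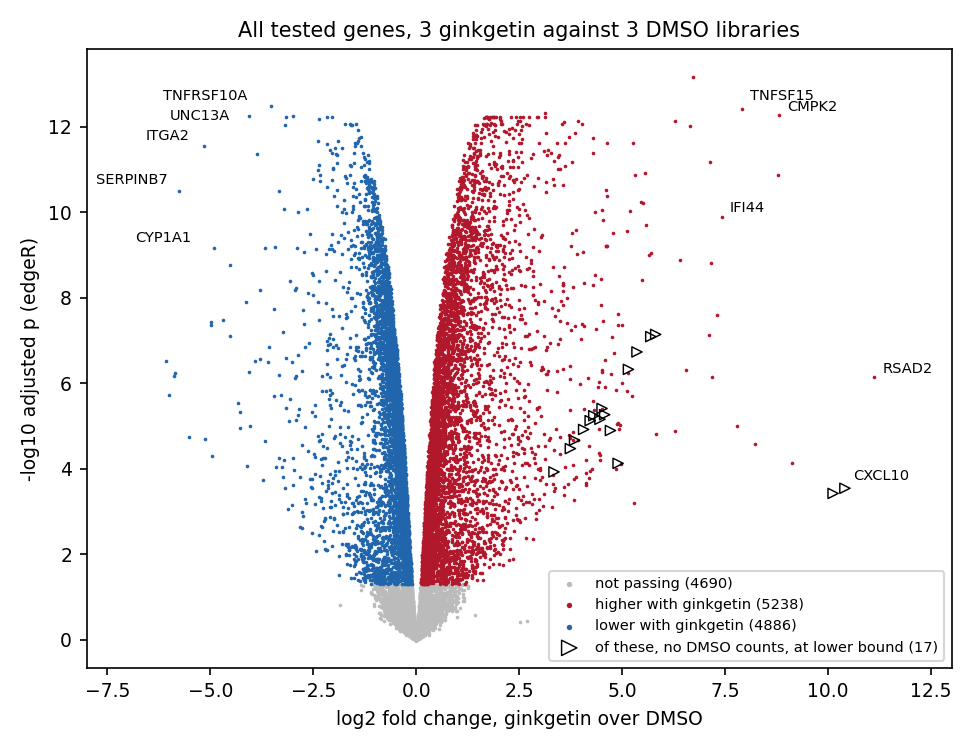
Each point is 1 of the 14814 tested genes, with the log2 fold change of ginkgetin over DMSO on the x axis and -log10 of the edgeR adjusted p on the y axis. Red points are the 5238 genes higher with ginkgetin, blue points the 4886 lower and grey points the 4690 not passing, and open triangles are the 17 changed genes without DMSO counts, drawn at their lower bound.

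Among the 10 largest rises taken by the rule for named genes, CXCL10, a chemokine that attracts T cells, had 0 counts in the DMSO libraries and 39.3 ± 10 CPM with ginkgetin, at least 1358-fold higher. CXCL10 (ENSG00000169245) lies on chromosome 4 from 76021117 to 76023497 in GRCh38. RSAD2 (ENSG00000134321; chromosome 2, 6865806 to 6898239) and CMPK2, a nucleotide kinase (chromosome 2, 6840570 to 6866635), are neighbours on opposite strands that share 14 exon bases. CMPK2 went from 0.198 ± 0.082 to 87.7 ± 13 CPM. The antiviral genes TRIM22, MX2 and IFI44 had log2 fold changes of 9.12 (SE 0.61), 8.22 (SE 0.45) and 7.41 (SE 0.16). TNFSF15, a TNF-family cytokine, had a log2 fold change of 7.90 (SE 0.20). C6, a component of the complement attack complex, had 1 count in the DMSO group, and its ratio was 568, with a 95% counting interval from 102 to 22470. TNFAIP6, a hyaluronan-binding protein induced by TNF, had 2 counts in the DMSO group and a ratio of 266, with an interval from 73.5 to 2203. The pseudogene GBP1P1 had 0 DMSO counts and was at least 1112-fold higher, but it resembles the guanylate-binding protein genes, so reads from these may be counted there and its value is uncertain. All DMSO counts of TRIM22, C6 and TNFAIP6 were in DMSO replicate 3, and without it these genes were at least 1265-fold, 125-fold and 111-fold higher. Without DMSO replicate 1 the log2 fold change of TRIM22 was 8.47 and the ratio of TNFAIP6 was 169, with an interval from 46.6 to 1396. Without DMSO replicate 2 the log2 fold change of RSAD2 was 11.74. Adjusted p-values of these 10 genes lay between 3.82e-13 and 0.000379 in edgeR's test.

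The largest of the 10 falls taken by the same rule was that of SERPINB7, a serine protease inhibitor, from 5.99 ± 0.52 to 0.112 ± 0.072 CPM, a log2 fold change of -5.75 (SE 0.28). ITGA2, the alpha 2 subunit of a collagen-binding integrin, fell from 13.96 ± 1.4 to 0.409 ± 0.16 CPM. CYP1A1, the cytochrome induced by the aryl hydrocarbon receptor, fell from 2.99 ± 0.049 to 0.101 ± 0.038 CPM. TNFRSF10A, a death receptor for TRAIL (chromosome 8, 23190452 to 23225126), fell from 26.7 ± 0.46 to 2.33 ± 0.12 CPM, a log2 fold change of -3.52 (SE 0.09). UNC13A, a synaptic vesicle priming factor, and PADI3, a peptidylarginine deiminase, fell to 1.16 ± 0.098 and 0.835 ± 0.18 CPM from 19.4 ± 1.5 and 12.1 ± 0.95 CPM. BICDL1, SORL1, CR1 and MECOM complete the 10, with log2 fold changes of -4.53, -3.79, -3.68 and -3.46. Adjusted p-values of these 10 genes lay between 3.35e-13 and 1.82e-08 in the same test.

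Of the 8 fixed stellate cell genes, 6 were analysed here, and all 6 rose. ACTA2 (ENSG00000107796; chromosome 10, 88935074 to 88991339) had a log2 fold change of 3.28 (SE 0.13). It shares 12.8% of its exon bases with FAS on the opposite strand, which rose from 6.19 to 7.90 CPM. TGFB1, the main profibrotic cytokine, rose from 21.04 ± 3.4 to 68.7 ± 6.0 CPM, and CCN2, a matricellular growth factor, from 124 ± 0.59 to 287 ± 18 CPM. TIMP1, an inhibitor of matrix proteases, rose from 95.5 ± 7.1 to 174 ± 4.2 CPM. COL1A2, a chain of type I collagen (ENSG00000164692; chromosome 7, 94394561 to 94431232), rose from 1546 ± 65 to 2343 ± 243 CPM, a log2 fold change of 0.60 (SE 0.07). PDGFRB, a receptor for platelet-derived growth factor, had 0 DMSO counts and 0.574 ± 0.094 CPM with ginkgetin, at least 19.8-fold higher. COL1A1 and COL3A1 were not analysed here.

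**Figure D2:**
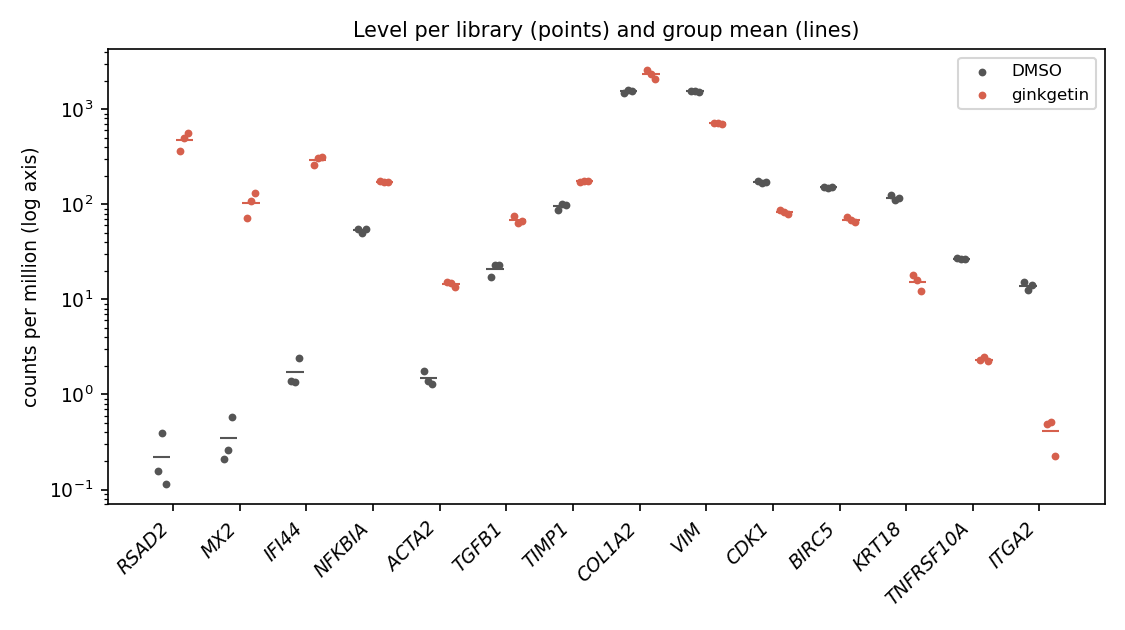
Levels of 14 genes in CPM on a log axis, with 1 point per library (grey DMSO, red ginkgetin, 3 libraries each) and a line at each group mean. The groups are apart for every gene shown, from RSAD2 at 0.221 and 476 CPM to ITGA2 at 13.96 and 0.409 CPM.

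In the list of activated stellate cell genes 15 of 19 tested members rose, 2 fell and 2 did not pass (camera adjusted p = 0.00199; adjusted p = 0.458 with an estimated correlation). LOX, which crosslinks collagen, had a log2 fold change of 1.06 (SE 0.05), whereas VIM, the intermediate filament vimentin, fell from 1542 ± 21 to 715 ± 7.6 CPM. Of 16 collagen chains 11 rose, 1 fell and 4 did not pass (camera adjusted p = 0.00603; adjusted p = 0.522 with an estimated correlation). COL4A2 of basement membranes rose from 296 ± 17 to 905 ± 19 CPM and COL5A2 from 875 ± 37 to 2103 ± 66 CPM, while the transmembrane collagen COL13A1 fell from 23.8 ± 2.7 to 8.45 ± 0.68 CPM. In collagen processing 22 of 29 genes rose, 1 fell and 6 did not pass (camera adjusted p = 4.49e-06; adjusted p = 0.458 with an estimated correlation). CRTAP and P3H1, which modify collagen prolines, had log2 fold changes of 1.82 (SE 0.06) and 1.45 (SE 0.05), SERPINH1, the collagen chaperone, 1.65 (SE 0.06), and FKBP14 -1.20 (SE 0.13). Of 31 matrix glycoproteins 22 rose, 3 fell and 6 did not pass (camera adjusted p = 0.00017; adjusted p = 0.458 with an estimated correlation). The basement membrane proteoglycan HSPG2 rose from 3.82 ± 0.57 to 33.1 ± 1.4 CPM and FBLN2 from 155 ± 12 to 589 ± 27 CPM, while NID2 fell from 33.5 ± 1.9 to 8.14 ± 0.60 CPM. The value of NID2 is uncertain, since it shares 29.96% of its exon bases with RTRAF on the opposite strand. RTRAF fell from 121 to 89.2 CPM. Of 36 TGF-beta targets 25 rose, 5 fell and 6 did not pass (camera adjusted p = 0.000272; adjusted p = 0.354 with an estimated correlation). TGFBR1, a TGF-beta receptor, and ADAM12, a metalloprotease, had log2 fold changes of 1.43 (SE 0.05) and 1.40 (SE 0.06), and HMGA2 -1.41 (SE 0.14). Adjusted over the list alone, 12 collagens rose, and the counts of the other 4 lists did not differ from those given.

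Of 17 tested interferon-stimulated genes 17 rose, with a median log2 fold change of 5.13 (camera adjusted p = 9.29e-09; adjusted p = 0.458 with an estimated correlation). The list held 49 genes, of which the other 32 were not analysed here, so the count covers the 17 alone. IRF7, a transcription factor of the interferon response, rose from 4.48 ± 0.056 to 39.2 ± 2.9 CPM and PSMB8, a subunit of the immunoproteasome, from 39.1 ± 0.76 to 122 ± 6.2 CPM. HLA-C, which presents peptides to T cells, had a log2 fold change of 1.78 (SE 0.06), a value that is uncertain because its reads can be shared with other HLA genes. In the list of NF-kappaB and cytokine genes 33 of 39 rose, 2 fell and 4 did not pass (camera adjusted p = 8.9e-08; adjusted p = 0.522 with an estimated correlation). NFKBIA, the inhibitor that NF-kappaB itself induces, rose from 53.4 ± 2.8 to 173 ± 0.93 CPM, the adhesion molecule ICAM1 from 17.2 ± 0.70 to 62.2 ± 1.8 CPM and BIRC3 from 14.04 ± 1.3 to 71.3 ± 6.4 CPM. The chemokine CXCL5 fell from 416 ± 15 to 291 ± 26 CPM. Immediate early transcription factors rose in 18 of 25 cases, fell in 4 and did not pass in 3 (camera adjusted p = 0.0169; adjusted p = 0.566 with an estimated correlation). KLF6 and FOSL2 had log2 fold changes of 1.34 (SE 0.06) and 1.10 (SE 0.05), and SRF -0.58 (SE 0.06). Adjusted over the list alone, the counts of these 3 lists did not differ from those given.

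**Figure D3:**
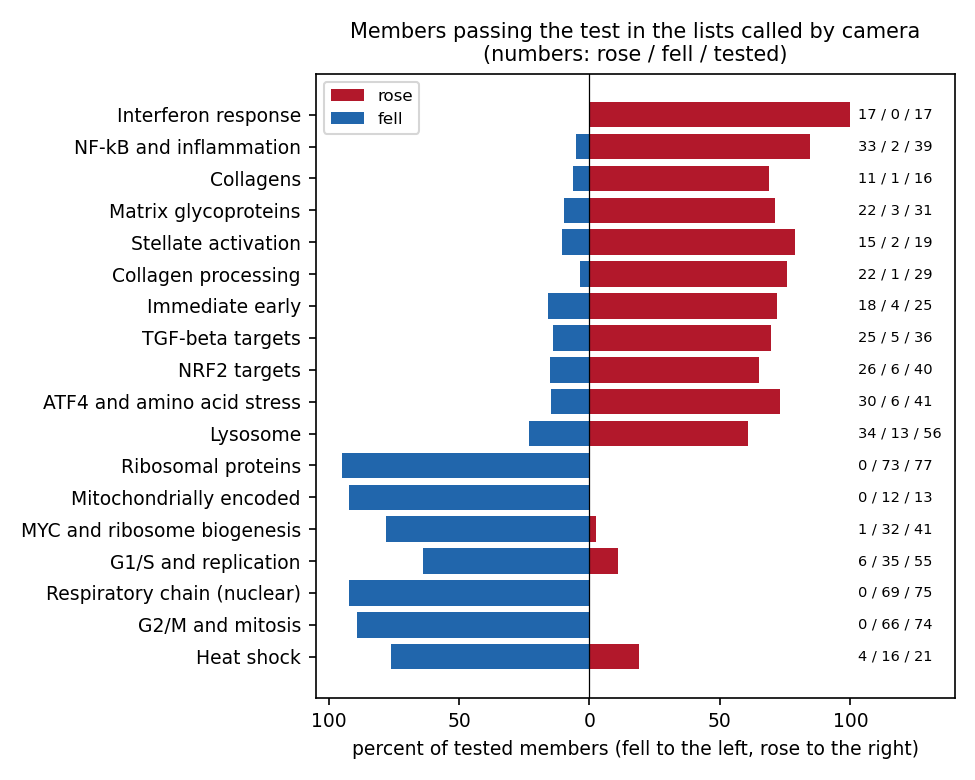
For each of the 18 lists called by camera, bars give the percent of tested members that rose (red, to the right) or fell (blue, to the left), and the numbers give members that rose, fell and were tested. Interferon genes rose in 17 of 17 cases, and 66 of 74 genes of mitosis fell with 0 rising, while with an estimated correlation 0 of the 35 tested lists passed, at a smallest adjusted p of 0.354.

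Of 74 genes of the G2/M transition and mitosis 66 fell, 0 rose and 8 did not pass, with a median log2 fold change of -0.76 (camera adjusted p = 9.06e-15; adjusted p = 0.458 with an estimated correlation). NDC80 of the kinetochore fell from 175 ± 6.7 to 79.3 ± 0.74 CPM and BIRC5, survivin, from 151 ± 1.6 to 68.7 ± 4.7 CPM. Of 55 genes of the G1/S transition and DNA replication 35 fell, 6 rose and 14 did not pass (camera adjusted p = 5.75e-05; adjusted p = 0.538 with an estimated correlation). CDC25A, a phosphatase that activates cyclin-dependent kinases, and DSCC1, which helps load the replication clamp, had log2 fold changes of -1.61 (SE 0.07) and -2.05 (SE 0.09). POLA1, a DNA polymerase subunit, rose from 56.2 ± 1.6 to 77.2 ± 2.7 CPM. In ribosome biogenesis 32 of 41 MYC targets fell, 1 rose and 8 did not pass (camera adjusted p = 1.49e-07; adjusted p = 0.432 with an estimated correlation). ODC1, the first enzyme of polyamine synthesis, fell from 167 ± 6.8 to 73.2 ± 3.5 CPM, and HSPD1, the mitochondrial chaperonin, from 859.8 ± 32 to 478 ± 8.8 CPM. The 1 riser was WDR43 (log2 fold change 0.13, SE 0.06), whose adjusted p of 0.048 lay between 0.0101 and 0.739 under the other settings and missed 0.05 in 13 of them. Of 77 ribosomal proteins 73 fell, 0 rose and 4 did not pass, with a median of -0.39 (camera adjusted p = 9.88e-12; adjusted p = 0.522 with an estimated correlation). FAU and RPL23 had log2 fold changes of -0.82 (SE 0.06) and -0.75 (SE 0.05), values that are uncertain since ribosomal protein genes share reads with processed pseudogenes.

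Of 75 nuclear-encoded respiratory chain subunits 69 fell, 0 rose and 6 did not pass, with a median of -0.55 (camera adjusted p = 1.93e-13; adjusted p = 0.458 with an estimated correlation). NDUFB9 and NDUFA12 of complex I fell from 165 ± 2.0 to 81.7 ± 3.4 CPM and from 79.8 ± 4.1 to 35.7 ± 0.88 CPM. Of 13 mRNAs of the mitochondrial genome 12 fell, 0 rose and 1 did not pass (camera adjusted p = 0.00249; adjusted p = 0.595 with an estimated correlation). MT-ND2 fell from 1575 ± 88 to 997 ± 72 CPM and MT-CO2 from 3455 ± 56 to 2329.8 ± 169 CPM. Mitochondrial mRNAs took 3.39%, 3.40% and 3.32% of the counts in the DMSO libraries and 2.78%, 2.37% and 2.68% in the ginkgetin libraries. The call on the mitochondrial list ended with an offset for transcript length and GC content, at an adjusted p of 0.0523 for the longest and 0.0659 for the principal transcript. Adjusted over the list alone, 67 mitotic genes, 36 G1/S genes, 74 ribosomal proteins and 70 nuclear-encoded respiratory chain genes fell, and the counts of the ribosome biogenesis and mitochondrial lists did not differ from those given.

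Among stress responses, 30 of 41 targets of ATF4 rose, 6 fell and 5 did not pass (camera adjusted p = 0.00219; adjusted p = 0.615 with an estimated correlation). JDP2, an AP-1 repressor, rose from 1.36 ± 0.40 to 16.5 ± 1.3 CPM and the amino acid transporter SLC1A4 from 8.33 ± 0.13 to 34.4 ± 4.1 CPM, whereas SLC7A5, a large neutral amino acid transporter, fell from 1608 ± 76 to 683 ± 23 CPM. Of 40 antioxidant targets of NRF2, 26 rose, 6 fell and 8 did not pass (camera adjusted p = 0.00665; adjusted p = 0.458 with an estimated correlation). EPHX1, an epoxide hydrolase, HMOX1, heme oxygenase, and NQO1 had log2 fold changes of 2.30 (SE 0.07), 1.78 (SE 0.07) and 1.06 (SE 0.05), and TXN, thioredoxin, -0.83 (SE 0.05). Of 56 lysosomal genes 34 rose, 13 fell and 9 did not pass (camera adjusted p = 0.00705; adjusted p = 0.566 with an estimated correlation). SCARB2 and LIPA, the lysosomal acid lipase, rose from 176 ± 3.1 to 486 ± 18 CPM and from 83.7 ± 1.9 to 200.2 ± 2.5 CPM, while ATP6V1B2 of the proton pump fell from 253 ± 3.3 to 108 ± 5.7 CPM. Of 21 genes of the heat shock chaperone list 16 fell, 4 rose and 1 did not pass (camera adjusted p = 0.00175; adjusted p = 0.588 with an estimated correlation). FKBP4, a cochaperone of HSP90, fell from 276 ± 2.0 to 129 ± 8.0 CPM, and HSPB1 rose from 161 ± 11 to 311 ± 21 CPM. Adjusted over the list alone, 35 lysosomal genes rose, and the counts of the other 3 lists did not differ from those given.

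Camera did not call the other 17 tested lists, and each is given with its camera adjusted p and the adjusted p with an estimated correlation. Chaperones of the endoplasmic reticulum were nearest, with 22 of 41 higher, 10 lower and 9 not passing (adjusted p = 0.053; adjusted p = 0.595 with an estimated correlation). Camera called them in 3 of the other settings, with library totals alone (adjusted p = 0.0485), with no filter (adjusted p = 0.0157) and without ginkgetin replicate 3 (adjusted p = 0.0207). DNAJC10, a disulfide reductase, rose from 75.95 ± 3.1 to 188 ± 1.9 CPM and XBP1, a transcription factor of the unfolded protein response, from 151 ± 3.0 to 243 ± 15 CPM. In fatty acid and triglyceride synthesis 14 of 27 genes rose, 5 fell and 8 did not pass (adjusted p = 0.198; adjusted p = 0.615 with an estimated correlation). SCD, the stearoyl-CoA desaturase, rose from 3814 ± 142 to 10318 ± 1101 CPM and FADS2, another desaturase, from 314 ± 21 to 993 ± 127 CPM, while GPAM fell from 25.6 ± 2.2 to 14.2 ± 1.0 CPM. In cholesterol synthesis 13 of 31 rose, 7 fell and 11 did not pass (adjusted p = 0.494; adjusted p = 0.885 with an estimated correlation). STARD4, a sterol carrier, had a log2 fold change of 1.48 (SE 0.06) and ERG28 -0.75 (SE 0.09). In fatty acid oxidation 10 of 29 rose, 15 fell and 4 did not pass (adjusted p = 0.473; adjusted p = 0.812 with an estimated correlation). CPT1C rose (log2 fold change 0.90, SE 0.07) and ECI1 fell (-0.69, SE 0.07), and the list's median of -0.18 and mean of 0.0035 differed in sign. Among regulators of apoptosis 17 of 35 rose, 10 fell and 8 did not pass (adjusted p = 0.198; adjusted p = 0.509 with an estimated correlation). BCL2L1, a survival protein, fell from 136 ± 0.68 to 66.7 ± 2.1 CPM and BID, a proapoptotic protein, rose from 22.2 ± 0.57 to 52.4 ± 0.84 CPM. In the senescence list 14 of 29 rose, 8 fell and 7 did not pass (adjusted p = 0.254; adjusted p = 0.746 with an estimated correlation). CCL2, a monocyte chemokine, had a log2 fold change of 4.30 (SE 0.15) and PLAUR, the urokinase receptor, -1.42 (SE 0.05). Of 38 p53 targets 16 rose, 12 fell and 10 did not pass (adjusted p = 0.967; adjusted p = 0.965 with an estimated correlation). TP53INP1 and PERP had log2 fold changes of 2.58 (SE 0.09) and -1.92 (SE 0.08). The median and mean of the p53 list lay above 0 and camera's direction was up, whereas fry's direction was down.

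Of 26 matrix proteases and inhibitors 14 rose, 8 fell and 4 did not pass (adjusted p = 0.313; adjusted p = 0.615 with an estimated correlation). MMP16 fell from 163 ± 3.8 to 81.4 ± 0.98 CPM and ADAMTS4 rose from 67.5 ± 8.7 to 165 ± 5.0 CPM. Among 33 contractile genes 15 rose, 11 fell and 7 did not pass (adjusted p = 0.494; adjusted p = 0.871 with an estimated correlation). CNN3, a calponin, and ZYX, zyxin of focal adhesions, had log2 fold changes of 1.14 (SE 0.05) and 1.31 (SE 0.07). VIM, given above, was among the 11 that fell, with a log2 fold change of -1.11 (SE 0.05). Of 22 targets of YAP and TAZ, 11 rose, 6 fell and 5 did not pass (adjusted p = 0.494; adjusted p = 0.615 with an estimated correlation), with DOCK5 at -1.20 (SE 0.06) and PTPN14, a phosphatase that restrains YAP, at 0.79 (SE 0.05). In growth signalling 14 of 34 rose, 14 fell and 6 did not pass (adjusted p = 0.609; adjusted p = 0.871 with an estimated correlation). SPRY4, a feedback inhibitor of MAPK signalling, fell from 155 ± 3.0 to 51.3 ± 2.9 CPM and MET, the hepatocyte growth factor receptor, from 287 ± 16 to 95.7 ± 3.6 CPM. PDGFRB, given above, was among the 14 that rose. The median of that list was -0.12 and camera's direction down, and its mean was 0.20. Of 15 genes of quiescent stellate cells 3 rose, 4 fell and 8 did not pass (adjusted p = 0.928; adjusted p = 0.928 with an estimated correlation). RBP4, the retinol carrier, rose from 1.65 ± 0.37 to 16.8 ± 1.4 CPM, GATA6 fell from 73.3 ± 2.8 to 51.4 ± 1.4 CPM, and LRAT, which stores retinol as esters, fell from 2.28 ± 0.18 to 0.556 ± 0.12 CPM. Its median of 0.09 and mean of 0.17 lay above 0, as did fry's direction, and camera's direction was down. Of 14 targets of the aryl hydrocarbon receptor 7 rose, 6 fell and 1 did not pass (adjusted p = 0.897; adjusted p = 0.928 with an estimated correlation). NFE2L2, which encodes NRF2, rose from 68.4 ± 4.6 to 214 ± 22 CPM, and CYP1A1 and SLC7A5 fell. The list's median was 0.24 and its mean 0.01, and fry's direction was down.

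Iron handling and ferroptosis had 15 of 33 genes higher, 11 lower and 7 not passing (adjusted p = 0.672; adjusted p = 0.871 with an estimated correlation). CISD1, an iron-sulfur protein, had a log2 fold change of -1.07 (SE 0.06) and GCH1, which starts tetrahydrobiopterin synthesis, 1.93 (SE 0.12). Autophagy had 19 of 44 higher, 14 lower and 11 not passing (adjusted p = 0.675; adjusted p = 0.797 with an estimated correlation). OPTN, an autophagy receptor, and ULK2, a kinase that starts autophagy, had log2 fold changes of 1.44 (SE 0.06) and 1.32 (SE 0.08). Against the list's majority, ATG4A fell from 20.4 ± 0.38 to 8.27 ± 0.99 CPM. Hypoxia and glycolysis had 17 of 41 higher, 16 lower and 8 not passing (adjusted p = 0.815; adjusted p = 0.928 with an estimated correlation). PGAM1, a glycolytic enzyme, rose from 40.96 ± 1.3 to 150.4 ± 17 CPM, and ADM, adrenomedullin, fell from 30.1 ± 2.6 to 9.03 ± 1.1 CPM. Adjusted over the list alone, 15 matrix proteases and inhibitors rose, 12 cholesterol genes rose and 13 p53 targets fell, and the counts of the other 14 uncalled lists did not differ from those given.

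Markers of other cell types were low or moved both ways. Of 7 epithelial markers 2 rose, 3 fell and 2 did not pass (camera adjusted p = 0.494; adjusted p = 0.615 with an estimated correlation). KRT8 and KRT18, the simple epithelial keratins, fell from 55.8 ± 2.0 to 9.003 ± 1.8 CPM and from 117 ± 7.0 to 15.4 ± 3.0 CPM, while CDH1, E-cadherin, rose from 0.332 ± 0.13 to 3.78 ± 0.30 CPM. Both keratins have many pseudogenes and share 525 exon bases with each other, so their values are uncertain to that extent. Of 4 tested leukocyte markers 1 rose, 1 fell and 2 did not pass, of 3 endothelial markers 2 rose and 1 fell, and of 2 hepatocyte markers 1 rose and 1 did not pass, with the same counts adjusted over the list alone. Camera was not run on these 3 lists. PTPRC, a leukocyte phosphatase, went from 0.177 ± 0.074 to 0.902 ± 0.023 CPM, ENG, endoglin, from 0.733 ± 0.039 to 2.95 ± 0.28 CPM and SERPINA1, the hepatocyte antitrypsin, from 1.36 ± 0.092 to 2.71 ± 0.79 CPM. These genes were not taken by the rule for named genes, and the leukocyte and endothelial markers that fell are not named. The summed CPM of the tested leukocyte markers went from 3.54 to 3.03, of the endothelial from 3.10 to 5.18 and of the hepatocyte from 1.77 to 3.15.

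In 9859 of the 10124 changed genes all libraries of 1 group lay above all of the other, and over all tested genes this held for 71.7%, against 10% by chance. The authors' deposited test gives 9557 genes a false discovery rate under 0.05, 5023 above and 4534 below 0 on the log2 scale, and of the 9350 of these tested here 9346 changed in the same direction. A further 778 genes changed here at a deposited false discovery rate that was not under 0.05. With an estimated correlation 0 of the 35 lists passed in camera, 2 at an unadjusted p under 0.05, while fry, which does not compare a list with other genes, passed 32. With a log2 fold change of at least 1 as a further condition, 2791 genes were called.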

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

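The equal-depth run and both offsets for transcript length and GC content were chosen only after the data were seen. Of the changed genes of the report, 9841 of 10124 also passed with the replicate block, which called 9898 genes, 5143 higher and 4755 lower. No library correlated best with the library of its own number. The correlations between the groups all lay between -0.0575 and 0.0767, too near 0 to decide whether the replicate numbers pair the samples. Under the other scalings, tests, filters and offsets, and at an adjusted p under 0.01, the count of changed genes lay between 8798 and 10387, and without each library in turn between 9443 and 10200. The library left out gave 4882 to 5244 higher and 4561 to 4956 lower genes. A log2 fold change of at least 1 left 2791 genes, 1878 higher and 913 lower, by its own construction.

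Among the 10079 changed genes that could be tested with the principal length and GC offset, 157 changed sign, and the median log2 fold change of all genes moved to -0.09. With that offset 4471 genes were higher and 5778 lower. None of the 155 named genes reversed under the scalings, tests, filters, offsets, equal depth, the replicate block and left-out libraries, except that PDGFRB did not pass the stricter filter and has no value there. The 13 calls lost under these settings were all of WDR43, with log2 fold changes between 0.02 and 0.15 where the call was lost. The named genes were not followed at a log2 fold change of at least 1 or an adjusted p under 0.01.

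Camera called 17 to 19 lists under the scalings, filters, offsets, equal depth, the replicate block and left-out libraries. With an estimated correlation it called 0 of 35, 2 of them at an unadjusted p under 0.05, and fry called 32. For the TGF-beta targets the estimated correlation was -0.0023, below the preset 0.01, yet their unadjusted p in camera went from 7.77e-05 to 0.0101. A higher correlation therefore cannot be the cause for that list. For the other lists the cause was not tested. No list called by camera changed sign under these settings, whereas the median of the uncalled p53 list, 0.10, became -0.10 and -0.09 with the offsets. The mitochondrial mRNAs lost their call with the offsets: their median log2 fold change went from -0.43 to -0.32 (longest transcript) and -0.30 (principal transcript). Of the 16 collagens 10 rose and 3 fell with either offset, in place of 11 and 1. Their median log2 fold change went from 1.16 to 0.88 (longest transcript) and 0.90 (principal transcript).

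The counting floor of 3 counts over the DMSO group, 0.0289 CPM, limits the folds of genes without DMSO counts. In simulated data 66.6% of changes of 0.5 on the log2 scale were called. There 200 of 14814 genes changed, against 68.3% called in the real libraries, so that rate does not carry over.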

Other observations

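The genes of this paragraph and of the next were chosen only after their values were seen. IFNB1, interferon beta, had 0 DMSO counts and 1.498 ± 0.30 CPM with ginkgetin (SD, n = 3 libraries), at least 51.8-fold higher. IL6 rose from 8.09 ± 0.97 to 315 ± 132 CPM, CCL5 from 0.892 ± 0.24 to 129 ± 29 CPM and VCAM1, an adhesion molecule of activated endothelium, from 0.099 ± 0.041 to 13.8 ± 2.9 CPM. Among interferon-induced genes USP18, BST2 and GBP2 had log2 fold changes of 6.40 (SE 0.21), 5.47 (SE 0.17) and 5.13 (SE 0.19). B2M, the light chain of class I HLA molecules, rose from 381 ± 7.8 to 1155 ± 69 CPM.

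In all, 17 changed genes had 0 counts in the 3 DMSO libraries. Among them SELE, the endothelial selectin, was at least 35.6-fold higher, GPR84 at least 29.9-fold, the homeobox genes MEOX2 and MEOX1 at least 22.8-fold and 22.0-fold, and the cytokine IL34 at least 18.7-fold.

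The tests on leukocyte RNA, on transcript length and GC content and on fewer epithelial cells were chosen only after the results were seen. The equal-depth run used below was also added after the data were seen. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 10124 changed genes in edgeR and the highest other split 0. At an unadjusted p under 0.05 in edgeR the others gave 42 to 80 genes and the real split 10436. Each other split mixed the groups and so put the difference between them into the spread within its sides. Few calls there were fixed in advance, so this comparison does not decide on chance. As large a count of genes was reached by 1 split, the real one. For the lists the real split gave 18 and the highest other split 18, so 2 of the 10 splits gave as many. The mixed splits kept part of the difference between the groups, so this count does not decide on chance either.

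Of 17 tested interferon-stimulated genes 17 rose. At equal depth 17 of the 17 still rose, so these calls did not depend on the extra counts of the ginkgetin libraries. Thinning keeps the expected CPM, so the run cannot show more than that. The leukocyte markers made up 0.0927% of the summed CPM of the interferon genes in the ginkgetin libraries, between 3.09 and 3.45 CPM against 3.26 to 5.17 CPM in the DMSO libraries, which argues against RNA of leukocytes, although PTPRC, one of these markers, rose from 0.177 to 0.902 CPM. A response of the cells to the compound may account for the pattern, as a hypothesis. The labels give no batch, so other differences between the cultures were not tested.

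Among short transcripts of housekeeping genes, 73 of 77 ribosomal protein mRNAs, 69 of 75 nuclear-encoded respiratory chain mRNAs and 12 of 13 mitochondrial mRNAs fell. Of the 165 tested members 90.9% still fell with the principal length and GC offset, and 93.3% at equal depth. That offset also moved the median log2 fold change of all tested genes to -0.09. It raised the count of lower genes from 4886 to 5778, so the share that fell partly reflects the setting. Across genes, which are not independent replicates, the Spearman correlation of log2 fold change with principal transcript length was 0.16 and became 0.028 after that offset. With the principal offset the medians of the ribosomal protein and nuclear-encoded lists were -0.32 and -0.50, below the -0.09 of all genes. For these lists this argues against transcript length and GC content as the whole cause. The equal-depth run shows only that the calls did not depend on the extra counts, since thinning keeps the expected CPM. Lower transcription or stability of these housekeeping mRNAs may remain, untested. The mitochondrial list on its own lost its call with the principal offset, where 11 of 13 still fell, the median log2 fold change was -0.30 in place of -0.43 and the camera adjusted p was 0.0659 in place of 0.00249.

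The keratins KRT8 and KRT18 fell. Of the 7 tested epithelial markers 3 fell, 2 rose and 2 did not pass. The risers CDH1 and CLDN4 had 0.332 and 2.28 CPM in the DMSO libraries, against 55.8 and 117 CPM for KRT8 and KRT18, so these 2 do not decide on fewer epithelial cells, which stays open. With 116 pseudogene entries added, the summed CPM of both keratins still had a log2 fold change of -2.38, which argues against reads moved to keratin pseudogenes. Both genes share 525 exon bases on opposite strands, 16.3% of those of KRT18 and 7.63% of those of KRT8, so reads of either may be counted in the other.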
